A study of Mus musculus and Homo sapiens with 52 samples.

How the data were processed

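RNA was measured in 36 samples of 16 groups (3 per 4T1 group, 2 per other group) and open chromatin in 16 samples of 6 groups (3 per 4T1 group, 2 per BMM group), 52 samples in all. Per the labels' protocols, RNA libraries were made with a TruSeq Stranded Total RNA kit and sequenced for 150 cycles on a HiSeq instrument, and ATAC libraries were sequenced paired-end on a NextSeq instrument. Per the submitters' processing notes, Bowtie2 2.4.5, SAMtools 1.3, Picard, MACS2 and DESeq2 were used with the builds GRCh37 (hg19) and GRCm38 (mm10), with no role given to each tool. Groups and replicate numbers were taken from the sample titles.

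Per the file headers, the deposited RNA tables hold expected counts per RefSeq transcript, made with HOMER over exons on both strands without scaling. The values come in steps of 0.5, and a read counts in every isoform it overlaps. Because strand is ignored, overlapping genes on opposite strands cannot be told apart. The deposited FPKM tables hold FPKM per transcript, scaled by the total that the count file's header gives, per the file headers. In the authors' deposited ATAC tables for 4T1, each region has a signal and a log2 signal per group, a ratio of control over knockdown given as a fold change, and a p-value that is not adjusted and whose test is not stated. In the authors' deposited ATAC table for BMM, each region has a log2 fold change, a shrunk log2 fold change, a p-value and an adjusted p-value, and the numerator is not stated. The control names are crossed in the 4T1 ATAC tables: per the sample descriptions, the control column headed vec (shMYADM#1 table) holds the samples titled shContral and that headed shCtrl (shRhoA table) the samples titled Vector, and the descriptions were followed. What the ATAC signal is relative to is not stated either, and no value per library was used for ATAC.

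Each gene was represented by its transcript with the most reads, which left 25124 mouse and 28243 human genes from 42361 and 70488 transcripts. Transcripts with no gene name (91 in mouse, 406 in human) held 0.0328 to 0.796% of counts in a table and were left out. Counts falling on genes ran from 15.5 to 21.0 M reads per library in 4T1, 19.7 to 28.3 M in BMM, 17.1 to 21.0 M in MCF10A, 18.0 to 27.8 M in ACHN and 29.5 to 37.2 M in CL1. The common biological coefficient of variation was 0.159 in 4T1, 0.174 in BMM, 0.508 in MCF10A, 0.182 in ACHN and 0.0353 in CL1. Mitochondrial genes are not in the tables.

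Counts were rounded, filtered with filterByExpr, scaled by TMM and tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. All groups of a table shared 1 dispersion fit, without a replicate block. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, in 11 comparisons against control, wild type, vector, parental ACHN or CL1-0, and in 2 direct contrasts within 4T1. A set of 38 gene lists was tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) where at least 5 members were tested. Each list is also given with an estimated correlation and with calls adjusted over the list alone. A gene at 0 counts in a group is given as a bound against a floor of 3 counts over the group, and a gene with 1 to 3 counts as a ratio with a 95% counting interval. Medians of lists with such genes were also computed with these genes at their bound. Shared calls were set against independent calls and against 20 simulated unchanged sets of libraries that share their controls. Fold changes of 2 comparisons were compared by correlation and covariance.

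ATAC regions were read with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures were drawn with Matplotlib 3.10.9. Regions count as called at the authors' p under 0.05 in 4T1 and adjusted p under 0.05 in BMM. A promoter region lies within 1 kb of a start site, and promoters of genes with higher and lower RNA were compared with 1e+05 permutations of genes. Regions whose gene name reads as a number were not linked to genes.

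The genes that the text names follow a rule. It takes MYADM and RHOA, then for each list up to 3 called members with the largest change, at least 2 CPM in the higher group and no overlap between libraries, or the most abundant member where none is called. It adds the 6 highest and 6 lowest genes with at least 10 CPM (3 for each ACHN and CL1 line), ranked by the smaller change where comparisons are joined. Pseudogenes and predicted genes were skipped, and some genes and 1 gene list are not reported here. Of the genes the rule gives, those of lists with the smallest camera p come first, up to about 30 per comparison. For ATAC it takes the 3 highest and 3 lowest regions and those at MYADM and RHOA. The Dapk1 and Htatip2 promoter regions were chosen after their RNA values were seen.

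The design, the gene lists, the naming rule and 143 alternatives were fixed before the data were examined, and 7 alternatives were added afterwards. The alternatives were DESeq2 1.42.0 size factors and its Wald test, total-read scaling, no filter and a stricter filter at 1 CPM, limma on log2 FPKM with a pseudocount of 1 or 0.1 (mean FPKM of at least 0.5), the longest transcript, a replicate block, the 2 compared groups alone, 1.5-fold and 2-fold minimums, fry in limma, each library left out in turn, and stricter ATAC thresholds and wider windows (0.01 and 3 kb).

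The fit was tested on simulated data with known changes of 1.5, 2 and 4-fold among genes with each table's spread. Recovery was 32.8, 73.1 and 95.5% at the size of a 4T1 comparison (5 false among 166 calls), 11.9, 61.2 and 97.0% for BMM (11 false among 143), 9.0, 47.8 and 86.4% for ACHN (4 false among 110) and 85.1, 92.5 and 100% for CL1 (13 false among 227). For MCF10A it was 0% at every size, with 0 calls. The smallest exact permutation p is 0.1 for 3 against 3 samples and 0.333 for 2 against 2, so single values rest on the fitted models.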

Results

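RNA was sequenced in 36 samples and open chromatin profiled by ATAC-seq in 16. The mouse RNA covers 4T1 mammary carcinoma cells with a control shRNA, 2 shRNAs labelled against MYADM (a membrane protein of the MARVEL domain family) or an shRNA labelled against RhoA (a small GTPase that organises actin), with 3 samples each. It also covers bone marrow cells of wild-type and MYADM knockout mice grown for 5 days with 20 ng/ml M-CSF (BMM, 2 samples each). The human RNA, with 2 samples per group, covers MCF10A breast epithelial cells with a vector or MYADM overexpression, the kidney carcinoma line ACHN with its variants AK, AL and LL, and the lung cancer lines CL1-0, CL1-1, CL1-3 and CL1-5. Mapped reads per library ran from 18.4 to 24.7 M in 4T1, 20.5 to 29.5 M in BMM, 20.7 to 22.9 M in MCF10A, 20.8 to 31.3 M in ACHN and 31.2 to 39.4 M in CL1. Gene levels are counts scaled to library size (CPM, mean ± SD), changes are log2 fold changes ± SE, and a gene is called when its adjusted p (edgeR quasi-likelihood, Benjamini-Hochberg) lies under 0.05. The p-values measure the spread between these samples alone, since the labels do not say whether replicates were separate cultures or animals.

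The first question was whether the targeted transcripts moved in the direction of the labels. In 4T1, Myadm fell from 185 ± 6.59 to 91.6 ± 0.729 CPM with shMYADM#1, a change of -1.02 ± 0.07 (n = 3 each, edgeR adjusted p = 1.17e-06). In the libraries labelled shMYADM#2 Myadm stood at 166 ± 4.26 CPM, a change of -0.16 ± 0.07 that was not called (edgeR adjusted p = 0.0684). Rhoa stood at 569 ± 34 CPM in the controls and 527 ± 23.3 CPM in the libraries labelled shRhoA, a change of -0.11 ± 0.07 that was not called (edgeR adjusted p = 0.182), while Myadm rose there to 300.4 ± 18.8 CPM (0.70 ± 0.07, edgeR adjusted p = 6.17e-06). Rhoa rose with shMYADM#2 (0.25 ± 0.07, edgeR adjusted p = 0.00768) and was not called with shMYADM#1 (0.05 ± 0.07, edgeR adjusted p = 0.589). The transcript levels thus show a knockdown of the named target for shMYADM#1 alone, and protein was not measured here.

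**Figure D1:**
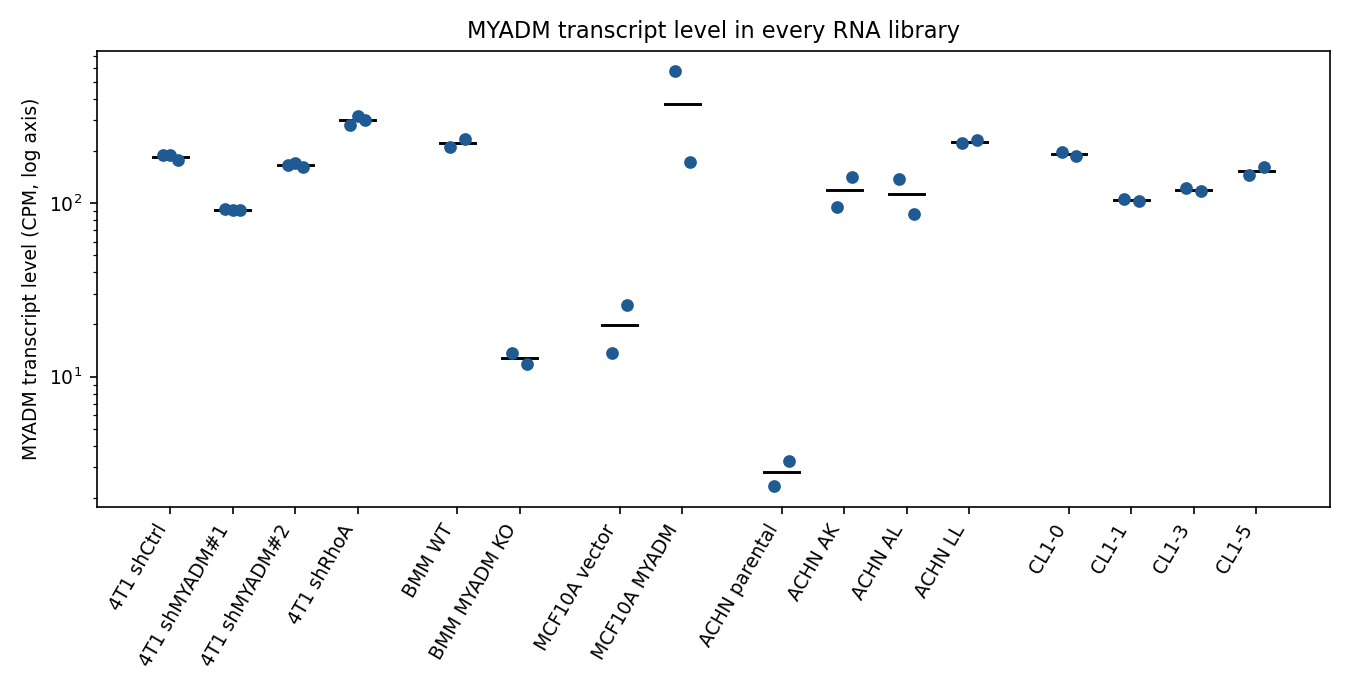
MYADM transcript level in each RNA library (points, log axis) and the mean of each group (black line). Each group holds 2 or 3 libraries.

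Comparing shMYADM#1 with control asks what accompanies a lowered Myadm transcript in 4T1 cells. Cholesterol synthesis genes rose, among them Idi1, an isoprenoid isomerase, from 3.32 ± 0.154 to 19.7 ± 2.87 CPM (2.57 ± 0.31), and the sterol demethylase Cyp51 (2.15 ± 0.10). The proliferation marker Mki67 rose from 80.1 ± 13.3 to 226 ± 15.5 CPM, with the mitotic checkpoint kinase Bub1 at 1.37 ± 0.34 and the replication helicase subunit Mcm5 at 1.33 ± 0.16. Interferon genes fell, with Ifi44 going from 12.0 ± 1.67 to 0.677 ± 0.239 CPM (-4.16 ± 0.41), the antiviral synthetase Oas3 changing by -3.18 ± 0.40 and the RNA sensor Ifit1 by -3.16 ± 0.25. Genes of hypoxia and glycolysis fell too, including the angiogenic factor Vegfa from 376 to 93.3 CPM (-2.01 ± 0.28), the enolase Eno2 (-2.90 ± 0.35) and the carbonic anhydrase Car9 (-2.39 ± 0.24). In all, 4395 of 12687 genes tested were called (34.6%), 2088 higher and 2307 lower, of which 593 and 759 changed at least 2-fold. Leaving out 1 library gave between 3312 and 3680 calls, and Mki67 lost its call without control replicate 1, 2 or 3 or shMYADM#1 replicate 2 or 3 (edgeR adjusted p = 0.0567, 0.093, 0.0651, 0.0666 and 0.0615).

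Gene lists place these genes in wider groups, and in every called list of the 11 comparisons the median, the mean and the test share their sign. Of the cell cycle genes, 27 of 32 rose and 0 fell (28 and 0 adjusted over the list alone) with a median of 0.90, and of the cholesterol genes 18 of 23 rose and 1 fell (19 and 1 adjusted over the list alone) with a median of 0.94. Targets of SRF and MRTF, transcription factors that answer to actin, rose for 15 of 23 genes and fell for 2 (15 and 2 adjusted over the list alone, median 0.56), with the matricellular genes Ccn1 (2.48 ± 0.32) and Ccn2 (2.00 ± 0.28) and the immediate early gene Fos (1.44 ± 0.24) changing most. Interferon genes fell for 22 of 29 and rose for 1 (22 and 1 adjusted over the list alone, median -1.14). The camera test in limma with Benjamini-Hochberg adjustment gave these lists an adjusted p of 1.3e-13, 2.29e-12, 5.41e-06 and 2.2e-08, and each kept its call with an estimated correlation (0.0283, 0.00745, 0.00745 and 0.00858).

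Hypoxia genes (21 of 29 lower, 1 higher, 23 and 1 adjusted over the list alone, median -0.86) passed camera at 2.83e-08, with an adjusted p = 0.389 with an estimated correlation. Stress response genes fell for 13 of 27 and rose for 1 (13 and 1 adjusted over the list alone, median -0.58), including the chaperone partner Sdf2l1 (-2.88 ± 0.15) and the lipoprotein receptor Vldlr (-1.80 ± 0.33), and camera gave 9.55e-05, or adjusted p = 0.127 with an estimated correlation. Epithelial genes rose for 15 of 32 and fell for 4 (17 and 4 adjusted over the list alone, median 0.42), including the trafficking GTPase Rab25 (4.07 ± 0.20) and the tight junction gene Cldn3 (2.13 ± 0.18), with camera at 9.55e-05, or adjusted p = 0.171 with an estimated correlation. Mesenchymal genes fell for 7 of 16 and rose for 2 (7 and 2 adjusted over the list alone), with a median of -0.67 (-0.48 with near-zero genes at their bound) against a mean of -0.16. The collagen Col5a1 fell by 3.14 on the log2 scale and the matrix gene Tnc rose by 3.85 ± 0.25, and camera gave the mesenchymal list 0.035, or adjusted p = 0.522 with an estimated correlation. The 10 lists not called had adjusted p of 0.184 to 0.984 by camera. In 3 of them the median and the mean differ in sign, namely MARVEL genes (0.13 and -0.58), caveolae genes (0.11 and -0.08) and chromatin regulators (-0.05 and 0.01).

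Other large rises with shMYADM#1 were in the kinase anchor Akap12 (3.67 ± 0.19), the tetraspanin Tspan1 (3.39 ± 0.24), the ion channel-like gene Tmem266 (3.21 ± 0.29), the myosin Myh14 (3.11 ± 0.35) and the membrane gene Prom2 (2.97 ± 0.11). The MARVEL family gene Mal2 was at 0 counts in all 3 knockdown libraries and at least 192-fold lower, against a floor of 3 counts over the group. The metastasis suppressor Htatip2 was lower 1130-fold (95% counting interval 312 to 9340), the ubiquilin Ubqln2 317-fold (95% counting interval 108 to 1540) and the death-associated kinase Dapk1 254-fold (95% counting interval 86.4 to 1230). The kinesin Kif21b changed by -5.93 ± 0.64, the TGF-beta co-receptor Tgfbr3 by -5.81 ± 0.31 and the neutrophil chemokine Cxcl3 by -4.79 ± 0.73. Intervals and floors cover counting error alone.

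**Figure D2:**
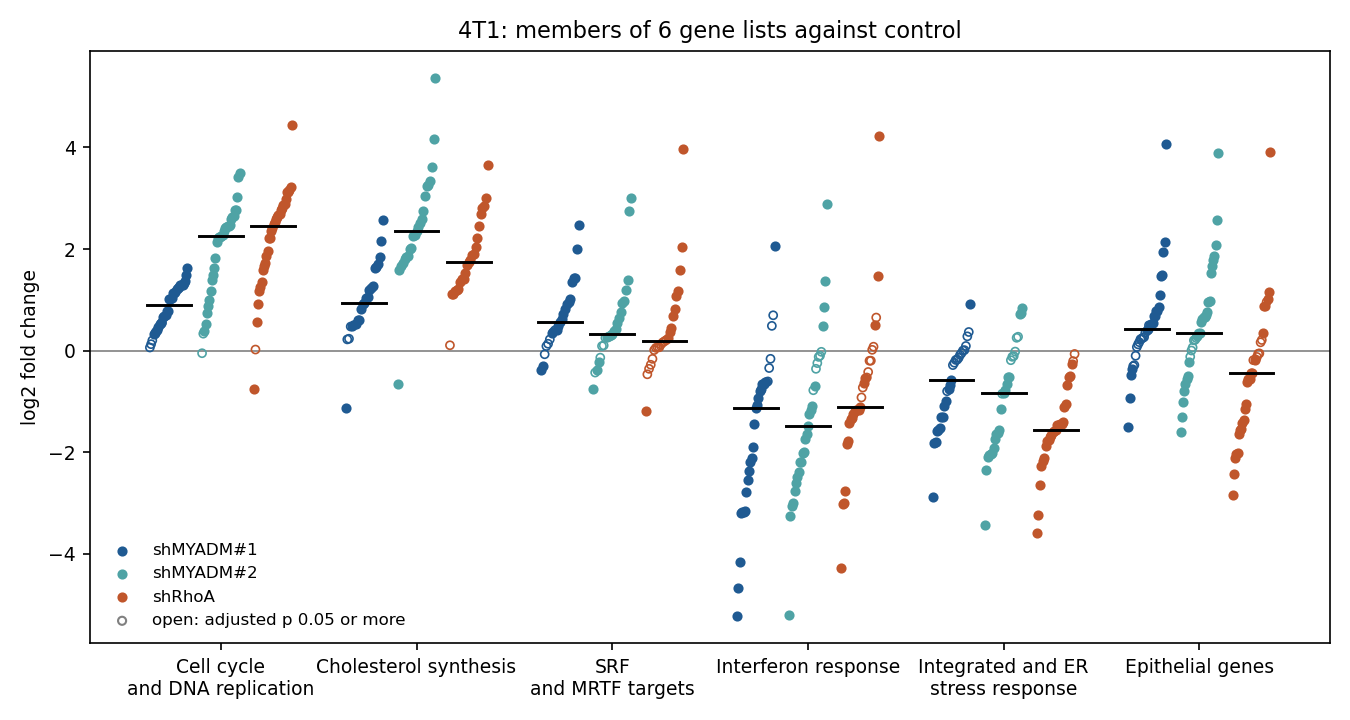
Log2 fold change against control of the members of 6 gene lists in the 3 knockdown-labelled 4T1 groups. Filled points have an edgeR adjusted p under 0.05, open points do not, and the black bar is the list median.

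Libraries labelled shMYADM#2 were compared with the same controls to ask which of these changes recur at a near-normal Myadm transcript level. Idi1 rose from 3.32 to 138 CPM (5.37 ± 0.32), Cyp51 by 4.17 ± 0.11 and the prenyl synthase Fdps by 3.61 ± 0.15. Cell cycle genes rose strongly, with the cyclin Ccne1 at 3.49 ± 0.33, Mki67 at 3.42 ± 0.49 and the nucleotide reductase subunit Rrm2 at 3.03 ± 0.10. The iron-binding inflammatory gene Lcn2 fell from 789 ± 122 to 9.61 ± 0.346 CPM (-6.36 ± 0.37), and the basal keratin Krt14 rose by 5.89 ± 0.26. In all 6567 genes were called (51.8% of 12687), 3090 higher and 3477 lower, with 1177 and 1325 at least 2-fold changed, and leaving out 1 library gave 5677 to 5995 calls.

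With shMYADM#2, 30 of 32 cell cycle genes rose and 0 fell (31 and 0 adjusted over the list alone, median 2.25, camera 1.68e-17) and 22 of 23 cholesterol genes rose and 1 fell (22 and 1 adjusted over the list alone, median 2.36, camera 4.22e-17). Both lists kept their calls, at adjusted p = 0.0278 and 0.00419 with an estimated correlation in limma. Interferon genes fell for 19 of 29 and rose for 4 (19 and 4 adjusted over the list alone, median -1.49), with Ifi44 at -3.25 ± 0.37 and the synthetase Oas1a at -3.06 ± 0.30 (limma camera 0.000337, or adjusted p = 0.0618 with an estimated correlation). Stress response genes fell for 17 of 27 and rose for 3 (17 and 3 adjusted over the list alone, median -0.83), with Sdf2l1 at -3.43 ± 0.15, the calcium chaperone Calr at -2.35 ± 0.07 and the co-chaperone Dnajb9 at -2.10 ± 0.26 (limma camera 0.000337, or adjusted p = 0.142 with an estimated correlation). SRF and MRTF targets rose for 15 of 23 and fell for 3 (15 and 3 adjusted over the list alone, median 0.32), including Ccn1 (3.01 ± 0.32), Ccn2 (2.75 ± 0.28) and the actin gene Actg1 (1.20 ± 0.15), with limma camera at 0.013, or adjusted p = 0.0618 with an estimated correlation. Epithelial genes rose for 17 of 32 and fell for 8 (17 and 8 adjusted over the list alone, median 0.34), with Rab25 at 3.89 ± 0.21 and the epithelial transcription factor Ehf at 2.57 ± 0.35 (limma camera 0.014, or adjusted p = 0.433 with an estimated correlation). Hypoxia genes fell for 12 of 29 and rose for 1 (12 and 0 adjusted over the list alone, median -0.28), including Eno2 (-2.83 ± 0.35), Vegfa (-2.41 ± 0.29) and Car9 (-2.13 ± 0.23). The hypoxia list passed limma camera at 0.0349, had an adjusted p = 0.776 with an estimated correlation, and was lost without control replicate 2 (adjusted p = 0.0569).

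Other large rises with shMYADM#2 were in the maltase Mgam, higher 245-fold (95% counting interval 67.4 to 2030), the transcription factor Myb (5.84 ± 0.39), Tnc (5.55 ± 0.24), the thioredoxin-binding gene Txnip (4.75 ± 0.31) and the protease inhibitor Serpinb2 (4.74 ± 0.64). Other large falls were in Dapk1 (-6.71 ± 0.43), Htatip2 (-6.49 ± 0.28), Mal2 (-6.30 ± 0.36), Kif21b (-6.29 ± 0.66), the complement protease C1s1 (-6.10 ± 0.67) and Tgfbr3 (-5.90 ± 0.31). The collagenase Mmp13 fell by 4.39 on the log2 scale, the integrin subunit Itgb7 by 5.89 and the focal adhesion gene Tns1 by 5.17. The remaining 12 lists had adjusted p of 0.108 to 0.799 by camera.

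Taking both MYADM shRNAs, 3528 genes were called in the same direction with each (1661 higher, 1867 lower) and 76 in opposite directions. Independent calls at these rates would share 1141. Shared rises include the growth factor Inhba (2.62 and 3.07), the Wnt antagonist Sfrp1 (2.81 and 2.95), the metalloprotease Adam12 (1.82 and 2.91) and the citron kinase Cit (1.25 and 2.16), with shMYADM#1 first. Shared falls include the raft scaffold Cavin2 (-3.84 and -3.01), the ligand Wnt10a (-3.39 and -4.48), the lysosomal marker Cd68 (-1.45 and -2.45) and the vascular receptor Flt1 (-1.19 and -1.10). Over all genes the fold changes of the shRNAs had a correlation of 0.847 and a covariance of 0.922, against 0.512 and 0.0394 in simulated sets that share only the control libraries. All comparisons share the 3 control libraries, which adds to the likeness between groups.

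A direct contrast of the libraries labelled shMYADM#2 and shMYADM#1 asks how far the groups with the same named target differ. Idi1 was higher with #2 by 2.81 ± 0.27 and Cyp51 by 2.02 ± 0.10, Mki67 by 1.92 ± 0.46 and Mcm5 by 1.09 ± 0.16. Txnip was higher by 4.44 ± 0.30, Krt14 by 3.70 ± 0.21 and Tnc by 1.70 ± 0.18, while Lcn2 was lower (-3.30 ± 0.32). Myadm was itself higher with #2 by 0.86 ± 0.07 (n = 3 each, edgeR adjusted p = 7.78e-06). Of 12687 genes 3833 were called (30.2%), 1882 higher and 1951 lower, with 484 and 389 at least 2-fold changed. Cell cycle genes were higher for 28 of 32 (median 1.22, limma camera 2.78e-18, 0.0257 with an estimated correlation) and cholesterol genes for 22 of 23 (median 1.41, limma camera 4.83e-22, 0.0016 with an estimated correlation). Hypoxia genes were higher for 14 of 29 and lower for 2 (limma camera 0.00867, or adjusted p = 0.754 with an estimated correlation), and stress response genes were lower for 11 of 27 and higher for 1 (limma camera 0.017, or adjusted p = 0.629 with an estimated correlation). Without control replicate 2 and shRhoA replicate 1, which share the dispersion estimate, 7073 genes were called.

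Libraries labelled shRhoA were compared with control to ask which transcripts change alongside an Rhoa transcript that was not called. The chemokine Ccl2 rose from 1.10 ± 0.363 to 153 ± 5.97 CPM (7.11 ± 0.21), the chemokine Ccl7 was at 0 in all controls and at least 84.4-fold higher, and the cytokine Il6 was higher 103-fold (95% counting interval 28.1 to 853). The matrix genes Tnc (6.64 ± 0.25) and Col6a2 (5.04 ± 0.49) rose, and the proteoglycan Dcn was at least 39.7-fold higher. Ccne1 rose by 4.43 ± 0.32, the replication factor Cdc6 by 3.22 ± 0.14 and Idi1 by 3.65 ± 0.31. The stress regulators Atf5 (-3.58 ± 0.19) and Trib3 (-3.23 ± 0.12) fell, as did the tight junction gene Cldn4 (-2.43 ± 0.16), the casein Csn3 (-5.38 ± 0.46) and the Wnt receptor ligase Rnf43 (-4.89 ± 0.41). In all 6707 genes were called (52.9%), 3439 higher and 3268 lower, with 1381 and 1074 at least 2-fold changed, and leaving out 1 library gave 5793 to 8182. Scaling by total reads moves all of these changes by 0.104. Replicate 1 of shRhoA stands apart from replicates 2 and 3 in its profile, and control replicate 2 leans toward it.

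Stress response genes fell for 25 of 27 with shRhoA and rose for 0 (25 and 0 adjusted over the list alone, median -1.57, limma camera 2.96e-12, 0.0192 with an estimated correlation). Cell cycle genes rose for 30 of 32 and fell for 1 (30 and 1 adjusted over the list alone, median 2.45, limma camera 2.81e-17, 0.0192 with an estimated correlation), and cholesterol genes rose for 22 of 23 and fell for 0 (22 and 0 adjusted over the list alone, median 1.74, limma camera 1.07e-14, 0.00711 with an estimated correlation). Mesenchymal genes rose for 11 of 16 and fell for 2 (11 and 2 adjusted over the list alone, median 1.27), while epithelial genes fell for 18 of 32 and rose for 5 (18 and 7 adjusted over the list alone, median -0.44), with Rab25 rising by 3.92 ± 0.21. Limma camera gave these lists 0.00293 and 0.00404, or adjusted p = 0.24 and 0.24 with an estimated correlation. Interferon genes fell for 17 of 29 and rose for 3 (17 and 3 adjusted over the list alone, median -1.11), with Ifi44 at -3.01 ± 0.36 and the helper gene Rtp4 at -1.78 ± 0.18 (limma camera 0.00221, or adjusted p = 0.103 with an estimated correlation). Hypoxia genes rose for 19 of 29 and fell for 5 (19 and 6 adjusted over the list alone, median 0.55), among them the aldolase Aldoc (2.21 ± 0.29) and the glycolytic enzyme Gapdh (2.14 ± 0.62). The hypoxia list had limma camera adjusted p = 0.0165, adjusted p = 0.629 with an estimated correlation, and 0.055 and 0.0607 without shRhoA replicate 2 or 3, and Gapdh lost its call without replicate 2 (edgeR adjusted p = 0.051). Integrin and adhesion genes fell for 15 of 30 and rose for 4 (15 and 4 adjusted over the list alone, median -0.31), including Itgb7 (-2.54 ± 0.26) and the laminin receptor subunit Itgb4 (-1.92 ± 0.08). That list had limma camera adjusted p = 0.0355, adjusted p = 0.24 with an estimated correlation, and 0.104 without shRhoA replicate 1. The 11 remaining lists had adjusted p of 0.0619 to 0.832 by camera, with SRF and MRTF targets the nearest.

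Other large rises with shRhoA were in the creatine synthesis gene Gatm, higher 1100-fold (95% counting interval 197 to 43400), the cytokine Il33 (6.36 ± 0.87) and the placental hormone genes Prl2c4, higher 714-fold (95% counting interval 128 to 28200), and Prl2c3, higher 369-fold (95% counting interval 102 to 3050), whose near-identical copies leave the split of reads between them uncertain. Other large falls were in Dapk1 (-6.87 ± 0.45), the lysosomal enzyme Hexa (-5.30 ± 0.16), the vitamin D hydroxylase Cyp24a1 (-5.24 ± 0.42), the ion channel Trpv3 (-4.56 ± 0.25), the zinc finger gene Zfp57 (-4.54 ± 0.18) and the hormone Stc2 (-3.98 ± 0.18).

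Across all 3 knockdown-labelled groups, 2067 genes were called in the same direction (1018 higher, 1049 lower), where calls independent in all 3 would share 300.7. That number ignores the likeness of the 2 shMYADM groups, so it understates what shRhoA would share with them by chance. Rises shared by the 3 groups include Ccn1 (2.48, 3.01 and 3.98, in the order shMYADM#1, shMYADM#2, shRhoA), Rab25 (4.07, 3.89 and 3.92) and Idi1 (2.57, 5.37 and 3.65). Ifi44 (-4.16, -3.25 and -3.01) and Sdf2l1 (-2.88, -3.43 and -2.65) fell in each. The fold changes of shRhoA correlated with those of shMYADM#1 at 0.299 (covariance 0.302) and of shMYADM#2 at 0.511 (covariance 0.637). Simulated sets that share only the control libraries gave correlations of 0.515 and 0.518 and lower covariances of 0.0397 and 0.0398. They hold no changed genes, so only the covariances can be compared.

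A direct contrast of shRhoA with the mean of both shMYADM groups asks where the named targets part. Ccl2 was higher by 10.55 ± 0.20, the collagen Col6a1 by 5.32 ± 0.14 and the protease inhibitor Serpine2 by 3.63 ± 0.10. Hexa (-5.58 ± 0.15), Tspan1 (-5.02 ± 0.27) and Prom2 (-2.77 ± 0.10) were lower. Of 12687 genes 7137 were called (56.3%), 3922 higher and 3215 lower, with 1228 and 792 at least 2-fold changed. Hypoxia (25 of 29, median 1.34, limma camera 1.19e-07), mesenchymal (12 of 16, median 1.63, 0.000584), cytokine (20 of 31, 0.0114), interferon (14 of 29, 0.049) and cell cycle genes (25 of 32, 1.19e-07) were higher. Epithelial (26 of 32, median -0.91, limma camera 1.62e-09) and stress response genes (16 of 27, 0.000299) were lower. None of these 7 lists kept its call in limma, with adjusted p = 0.336, 0.282, 0.282, 0.282, 0.244, 0.144 and 0.244 with an estimated correlation, in the order given.

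In BMM the question was how bone marrow cultures differ without MYADM. Myadm fell from 223 ± 15.3 to 12.8 ± 1.31 CPM (-4.12 ± 0.20, n = 2 each, edgeR adjusted p = 6.9e-06), and Rhoa was not called (-0.20 ± 0.20, edgeR adjusted p = 0.482, or 0.028 without wild-type replicate 1). Macrophage genes fell, including the lipid carrier Apoe from 4183 ± 1340 to 1176 ± 119 CPM (-1.83 ± 0.25), the complement subunit C1qc (-1.78 ± 0.22) and the M-CSF receptor Csf1r from 3403 to 1404 CPM (-1.28 ± 0.20). Mast cell genes rose, with the protease Prss34 going from 3.10 ± 0.715 to 27.5 ± 9.91 CPM (3.15 ± 0.33) and the IgE receptor chain Fcer1a changing by 4.12 ± 0.51. Endothelial genes rose, with Pecam1 from 7.43 to 46.0 CPM (2.63 ± 0.25), the receptor Tie1 at 2.23 ± 0.28 and the junction gene Esam at 2.11 ± 0.27. The carbonic anhydrase Car2 (2.05 ± 0.35) and the globins Hba-a1 (3.06 ± 0.35) and Hba-a2 (3.08 ± 0.35), which share most of their reads, rose as well. Of 12855 genes 3232 were called (25.1%), 1811 higher and 1421 lower, with 1170 and 552 at least 2-fold changed. Leaving out 1 library moved that count to 1075 without knockout replicate 1, 908 without knockout replicate 2 and 6739 without wild-type replicate 2. Scaling by total reads moves all changes by 0.276, and limma on log2 FPKM values puts 78.8% of calls higher against 56.0%.

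Macrophage genes fell for 16 of 21 and rose for 0 (17 and 0 adjusted over the list alone, median -0.95, limma camera 2.01e-06). Mast cell and basophil genes rose for 7 of 7 and fell for 0 (7 and 0 adjusted over the list alone, median 3.02, limma camera 2.34e-06), endothelial genes for 8 of 11 and 0 (9 and 0 adjusted over the list alone, median 2.02, limma camera 2.34e-06) and erythroid genes for 6 of 7 and 0 (6 and 0 adjusted over the list alone, median 2.85, limma camera 2.1e-05). Cell cycle genes rose for 15 of 34 and fell for 1 (21 and 1 adjusted over the list alone, median 0.55, limma camera 0.000188), with the cyclin Ccnd1 from 148 to 467 CPM (1.66 ± 0.20), Bub1 at 1.22 ± 0.26 and Mki67 at 1.14 ± 0.25. TGF-beta pathway genes rose for 12 of 21 and fell for 3 (12 and 3 adjusted over the list alone, median 1.62, limma camera 0.00033), with the feedback gene Pmepa1 at 3.33 ± 0.48, the binding protein Ltbp1 at 3.10 ± 0.27 and the target Id1 at 3.00 ± 0.20. Hypoxia genes fell for 10 of 29 and rose for 1 (13 and 1 adjusted over the list alone, median -0.50, limma camera 0.000188), with the ankyrin gene Ankrd37 at -2.72 ± 0.29 and the oxygen sensor Egln3 at -1.77 ± 0.24. All 12 called BMM lists had an adjusted p = 0.376 with an estimated correlation in limma.

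The other 5 called lists had larger p-values. Pan-leukocyte genes fell for 7 of 14 and rose for 0 (9 and 0 adjusted over the list alone, median -0.58, limma camera 0.0082), a call lost without wild-type replicate 1 (0.0647) or knockout replicate 1 (0.226). Neutrophil genes rose for 7 of 17 and fell for 1 (8 and 1 adjusted over the list alone, median 0.36, limma camera 0.021, or 0.129 without wild-type replicate 2), with the granule enzymes Mpo at 2.28 ± 0.32 and Ctsg at 2.27 ± 0.32. Interferon genes fell for 3 of 30 and rose for 0 (0 and 0 adjusted over the list alone, median -0.28, limma camera 0.0212, or 0.143 without knockout replicate 1). Cholesterol genes fell for 6 of 23 and rose for 0 (6 and 0 adjusted over the list alone, median -0.19, limma camera 0.0467), with the squalene synthase Fdft1 at -1.43 ± 0.19, and were lost without wild-type replicate 2 (0.218) or knockout replicate 2 (0.203). MARVEL genes fell for 2 of 11 and rose for 0 (2 and 0 adjusted over the list alone, median -0.47, limma camera 0.0163, or 0.141 without knockout replicate 2). The remaining lists of at least 5 genes had adjusted p of 0.0743 to 0.699 by camera. Of smaller lists, 2 of 4 B cell genes and 1 of 2 T and NK cell genes fell (2 and 1 adjusted over the list alone).

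Among the genes that rose in the BMM knockout were the engulfment receptor Megf10 (4.00 ± 0.34), the stem cell antigen Ly6a (3.43 ± 0.34) and the Langerhans cell lectin Cd207 (3.42 ± 0.35), while the integrin subunit Itgb3 went from 98.9 to 528 CPM (2.42 ± 0.20). Genes that fell, besides Myadm, include the clock gene Dbp (-2.77 ± 0.22), the T cell co-receptor Cd4 (-2.70 ± 0.28), the selenium carrier Selenop from 3362 to 543 CPM (-2.63 ± 0.27) and the orphan receptor Gpr162 (-2.60 ± 0.27). Csf1r lost its call without knockout replicate 2 (edgeR adjusted p = 0.0654), Selenop without wild-type replicate 1 or 2 (0.137 and 0.109), and the abundant lysozyme gene Lyz2 (-0.95 ± 0.22) without knockout replicate 1 or 2 (0.304 and 0.231). The 10 most abundant genes hold 14.5% of counts in wild type and 10.0% in the knockout.

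**Figure D3:**
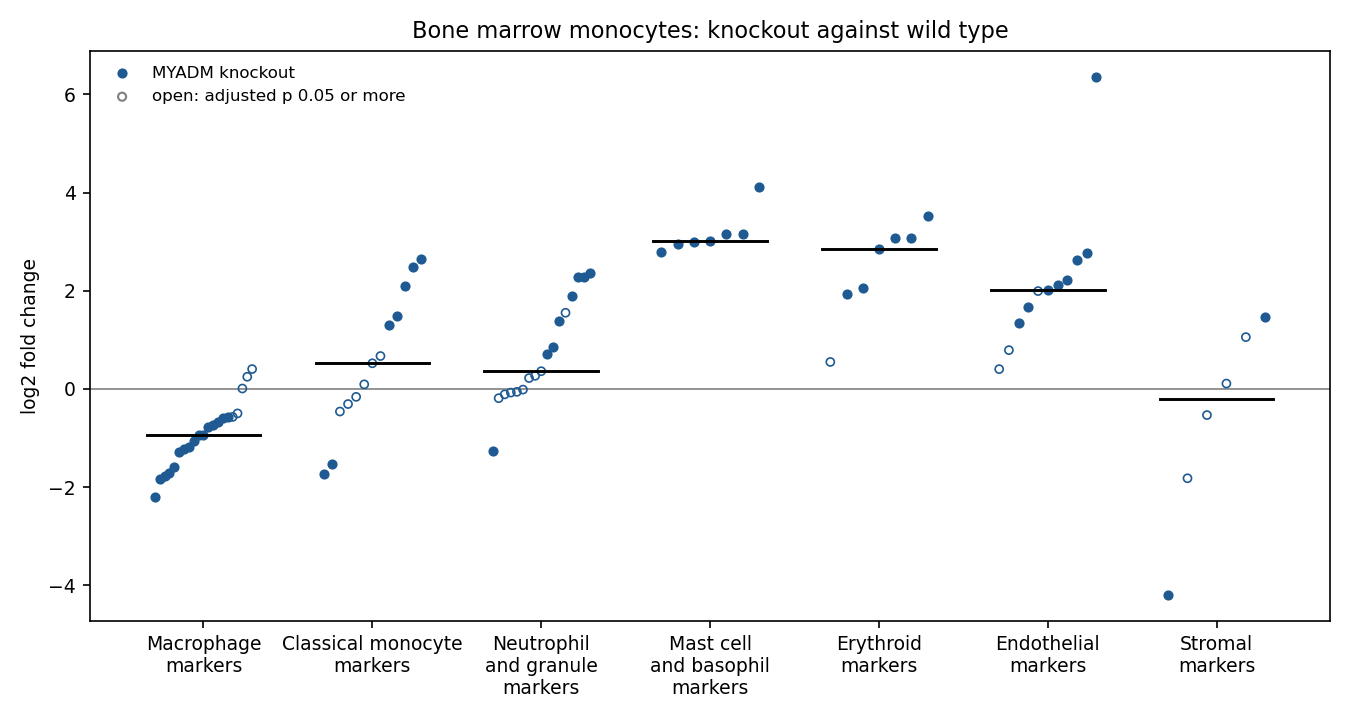
Log2 fold change of MYADM knockout against wild-type BMM for the members of selected gene lists. Filled points have an edgeR adjusted p under 0.05, open points do not, and the black bar is the list median.

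Genes called with both MYADM shRNAs in 4T1 were set beside the BMM knockout. Myadm was not called lower with shMYADM#2, so shared genes need not follow Myadm. Bub1 rose in each (1.37 with shMYADM#1 and 1.22 in BMM), and the lysosomal marker Cd68 fell in each (-1.45, -2.45 and -1.07), a BMM call lost without knockout replicate 1 or 2 (edgeR adjusted p = 0.104 and 0.11). Idi1 rose in 4T1 while Fdft1 of the same pathway fell in BMM (-1.43 ± 0.19). Over 11299 genes tested in both tables, 346 were higher in both against 175.5 expected (odds ratio 2.71) and 351 lower in both against 167.6 (odds ratio 3). Opposite directions held 231 against 347.2 expected. Genes of 1 pathway move together, so a Fisher test across genes (adjusted p = 5.4e-41 and 2.39e-48) overstates the evidence.

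MCF10A cells ask the reverse question, what follows when MYADM is raised. MYADM went from 19.8 ± 8.64 to 373 ± 283 CPM (4.24 ± 0.79, n = 2 each) and RHOA from 482 to 509 CPM (0.08 ± 0.43), and neither was called (edgeR adjusted p = 1 for both). The call depends on the model, since with a replicate block edgeR called MYADM (4.05, adjusted p = 0.022) and 432 genes in all, and the DESeq2 Wald test called it too (DESeq2 adjusted p = 4.64e-06). The lysosomal protease CTSB stood 1.36 ± 0.44 apart, the matrix gene FN1 1.24 ± 0.64 and the cytokine IL1B 0.82 ± 0.64, none of them called. The chaperone HSP90B1 (-0.32 ± 0.54), the catenin CTNNB1 (0.26 ± 0.42) and the actin ACTB (0.00 ± 0.61) were not called either. Of 15478 genes 0 were called by edgeR, with 162 at an unadjusted p under 0.05 (65 higher, 97 lower), and the DESeq2 Wald test called 16. Without MYADM replicate 1 edgeR called 16 genes and without MYADM replicate 2 it called 9, with MYADM itself at 4.85, and with the lone library assumed to vary like the other group. On simulated data of this spread 0% of 4-fold changes were recovered, so a count of 0 bounds nothing here.

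Replicate 1 of both MCF10A groups holds 14.7% and 14.1% of its counts in ribosomal protein genes (vector and MYADM) against 7.38% and 9.01% in replicate 2. Stress response genes had a median of -0.27 (limma camera 9.93e-05), SRF and MRTF targets 0.21 (0.008), cholesterol genes 0.21 (0.014) and Wnt pathway genes 0.18 (0.048). In each list 0 genes were called, and adjusted over the list alone 0 in the first 3 and 1 higher among Wnt genes. All 4 had an adjusted p = 0.877 with an estimated correlation in limma. Each lost its call when libraries were left out, the stress list without vector replicate 2 (0.351) or MYADM replicate 2 (0.323) and the SRF list without any of the 4 (0.0996, 0.171, 0.194 and 0.183, vector replicates first). The cholesterol list lost its call without vector replicate 2 (0.711), MYADM replicate 1 (0.0631) or MYADM replicate 2 (0.474), and the Wnt list turned lower without vector replicate 1 (0.927) or MYADM replicate 2 (0.877). The other lists had adjusted p of 0.0984 to 0.96 by camera. EdgeR called 0 genes opposite to the shared direction of the MYADM shRNAs in 4T1, against 12 at an unadjusted p under 0.05, where 8.76 are expected, beside 10 in the same direction, where 8.84 are expected.

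The ACHN variants were compared with parental ACHN to ask how derived kidney lines differ. MYADM stood at 2.82 ± 0.663 CPM in parental cells and at 118 ± 32.4 in AK, 113 ± 36.4 in AL and 226 ± 5.5 in LL (n = 2 each), rises of 5.40 ± 0.33, 5.33 ± 0.33 and 6.33 ± 0.34 with edgeR adjusted p of 0.00025, 0.000184 and 3.21e-05. RHOA was not called in any of the 3 (-0.17 ± 0.18, -0.04 ± 0.18 and 0.13 ± 0.18). Of 15832 genes tested, 84 were called in the same direction in all 3 lines (49 higher, 35 lower) where calls independent in all 3 would share 0.822. That number ignores the likeness between pairs of lines. In the order AK, AL and LL, the ciliary gene CYS1 rose by 4.09, 2.90 and 4.12, the hydrolase MACROD2 by 3.02, 3.94 and 4.67 and the zinc finger gene ZNF22 by 2.44, 2.54 and 2.96. The transcription factor TFAP2C changed by -2.19, -2.94 and -3.83, the ephrin receptor EPHA4 by -2.17, -4.37 and -6.40 and the hormone ERFE by -1.66, -3.13 and -3.43. Fold changes correlated at 0.784 between AK and AL, 0.602 between AK and LL and 0.746 between AL and LL (covariances 0.439, 0.405 and 0.706). Without parental replicate 2, the AK calls of ZNF22, TFAP2C, EPHA4 and ERFE were lost (edgeR adjusted p = 0.12, 0.285, 0.343 and 0.18), as they were without parental replicate 1 (0.0876, 0.17, 0.21 and 0.159) and, save for ZNF22, without AK replicate 2 (0.103, 0.226 and 0.103). CYS1 was lost in AK without parental replicate 1 (0.0509). All 3 comparisons share the 2 parental libraries, which alone gave correlations of 0.502, 0.491 and 0.486 and a covariance of 0.0714 in simulated sets.

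AK against parental cells asks what sets apart the variant nearest to its parent. The stress fibre gene RHOB fell from 400.4 ± 42.7 to 135 ± 0.0308 CPM (-1.57 ± 0.18), the raft gene CAVIN2 changed by -1.47 ± 0.15 and the collagen crosslinker LOX by -1.46 ± 0.24. The glucose transporter SLC2A3 rose by 1.57 ± 0.19 and the kidney transcription factor LHX1 by 2.21 ± 0.31. Of the cell cycle genes 0 of 34 rose and 0 fell (1 and 18 adjusted over the list alone, median -1.06, limma camera 1.97e-10, adjusted p = 0.925 with an estimated correlation). Cholesterol genes had 0 calls both ways and 0 adjusted over the list alone, with a median of 0.26 (limma camera 0.0456, adjusted p = 0.925 with an estimated correlation, 0.155 without parental replicate 2 and 0.607 without AK replicate 2). EdgeR called 97 genes (57 higher, 40 lower), 58.8% of them higher against 72.5% by limma with a pseudocount of 0.1, and 3076 genes had an unadjusted p under 0.05. Without parental replicate 1 edgeR called 2, without parental replicate 2 it called 4, without AK replicate 2 it called 16 and without AK replicate 1 it called 849. MYADM and MACROD2 were called each time, CYS1 was lost without parental replicate 1 (edgeR adjusted p = 0.0509) and RHOB without parental replicate 1 or 2 or AK replicate 2 (0.0991, 0.162 and 0.0776). So were CAVIN2 (0.0991, 0.161 and 0.0604), LOX (0.265, 0.238 and 0.239), SLC2A3 (0.159, 0.192 and 0.0535) and LHX1 (0.22, 0.234 and 0.056), in the same order. Haemoglobin genes hold 0.0431% of counts in AK replicate 1 and 0.0257% in parental replicate 2. The other lists had adjusted p of 0.157 to 0.873 by camera.

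AL was then compared with parental cells. MKI67 fell from 101 ± 23.1 to 8.69 ± 8.19 CPM (-3.51 ± 0.73), RRM2 changed by -3.49 ± 0.45 and the mitotic kinase PLK1 by -2.89 ± 0.50. The methylation reader UHRF1 (-2.80 ± 0.36) and the methyltransferase DNMT3B (-2.49 ± 0.28) fell, as did CIT (-2.65 ± 0.71). The vasopressin receptor AVPR2 rose by 5.29 ± 0.36, the adhesion receptor ICAM1 by 2.47 ± 0.45 and the collagen COL5A1 by 2.18 ± 0.28. The Wnt antagonist DKK1 was higher 82.9-fold (95% counting interval 22.6 to 690). Other large falls were in the transcription factor POU3F3 (-5.98 ± 0.42), the platelet kinase substrate PLEK (-5.35 ± 0.38) and the potassium channel KCNQ3 (-4.78 ± 0.37). EdgeR called 2416 genes (1158 higher, 1258 lower), with 644 and 830 at least 2-fold changed. Without parental replicate 1 or 2 it called 214 and 142, without AL replicate 1 it called 1412 and without AL replicate 2 it called 7104. MKI67 and CIT lost their calls without parental replicate 1 or 2 or AL replicate 1. PLK1 lost its call without parental replicate 2 or AL replicate 1, RRM2 without AL replicate 1 and ICAM1 without parental replicate 2. Limma on log2 FPKM values puts 38.9% of AL calls higher against 47.9%.

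Cell cycle genes fell in AL for 28 of 34 and rose for 1 (29 and 2 adjusted over the list alone, median -2.0, limma camera 2.4e-12). Chromatin regulators fell for 5 of 41 and rose for 1 (5 and 1 adjusted over the list alone, median -0.39, limma camera 0.0157, or 0.124 without AL replicate 1). Both lists had an adjusted p = 0.717 with an estimated correlation in limma, and the lists that camera did not call stood at 0.0557 to 0.962.

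In LL against parental cells, the cadherin CDH1 rose from 31.8 ± 2.69 to 333 ± 9.78 CPM (3.39 ± 0.54), the tight junction gene CLDN7 by 4.08 ± 0.46 and the calcium-binding gene S100A4 by 4.73 ± 0.54. Fibronectin FN1 fell from 1230 ± 245 to 56.2 ± 6.96 CPM (-4.45 ± 0.55). The membrane gene TMEM45B (7.53 ± 0.58), AVPR2 (6.49 ± 0.36) and the chemokine CCL2 (3.38 ± 0.31) rose, DKK1 was at least 46.2-fold higher and the cytokine IL1B was higher 262-fold (95% counting interval 72.1 to 2170). PLEK, POU3F3 and the fucosyltransferase FUT9 were at 0 counts in LL and at least 525-fold, 322-fold and 198-fold lower. RRM2 (-3.63 ± 0.46), CDC6 (-3.37 ± 0.36), MKI67 (-3.04 ± 0.72) and UHRF1 (-2.57 ± 0.36) fell, and the squalene synthase FDFT1 rose by 1.58 ± 0.19. EdgeR called 3527 genes (1821 higher, 1706 lower), with 1076 and 999 at least 2-fold changed, and 602 without LL replicate 1, 748 without LL replicate 2, 876 without parental replicate 1 and 859 without parental replicate 2. MKI67 lost its call without parental replicate 1 or 2 or LL replicate 1 or 2 (edgeR adjusted p = 0.085, 0.12, 0.113 and 0.134), and so did IL1B (0.132, 0.15, 0.0743 and 0.069). Scaling by total reads moves all LL changes by -0.131, and limma on log2 FPKM values puts 39.2% of calls higher against 51.6%.

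Cell cycle genes fell in LL for 29 of 34 and rose for 1 (31 and 1 adjusted over the list alone, median -1.81, limma camera 2.46e-11). Cholesterol genes rose for 11 of 24 and fell for 0 (12 and 0 adjusted over the list alone, median 0.64, limma camera 9.35e-05). Stress response genes fell for 10 of 27 and rose for 0 (10 and 0 adjusted over the list alone, median -0.54, limma camera 0.00131), chromatin regulators for 7 of 41 and 0 (6 and 0 adjusted over the list alone, median -0.40, limma camera 0.00226) and hypoxia genes for 5 of 29 and 1 (4 and 1 adjusted over the list alone, median -0.29, limma camera 0.0112). Cytokine genes rose for 9 of 26 and fell for 0 (10 and 0 adjusted over the list alone, median 0.60, limma camera 0.0274, or 0.0588 without LL replicate 1). With an estimated correlation limma gave adjusted p = 0.608, 0.608, 0.608, 0.608, 0.608 and 0.737, so none kept its call, and the other lists stood at 0.0921 to 0.88 by camera.

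**Figure D4:**
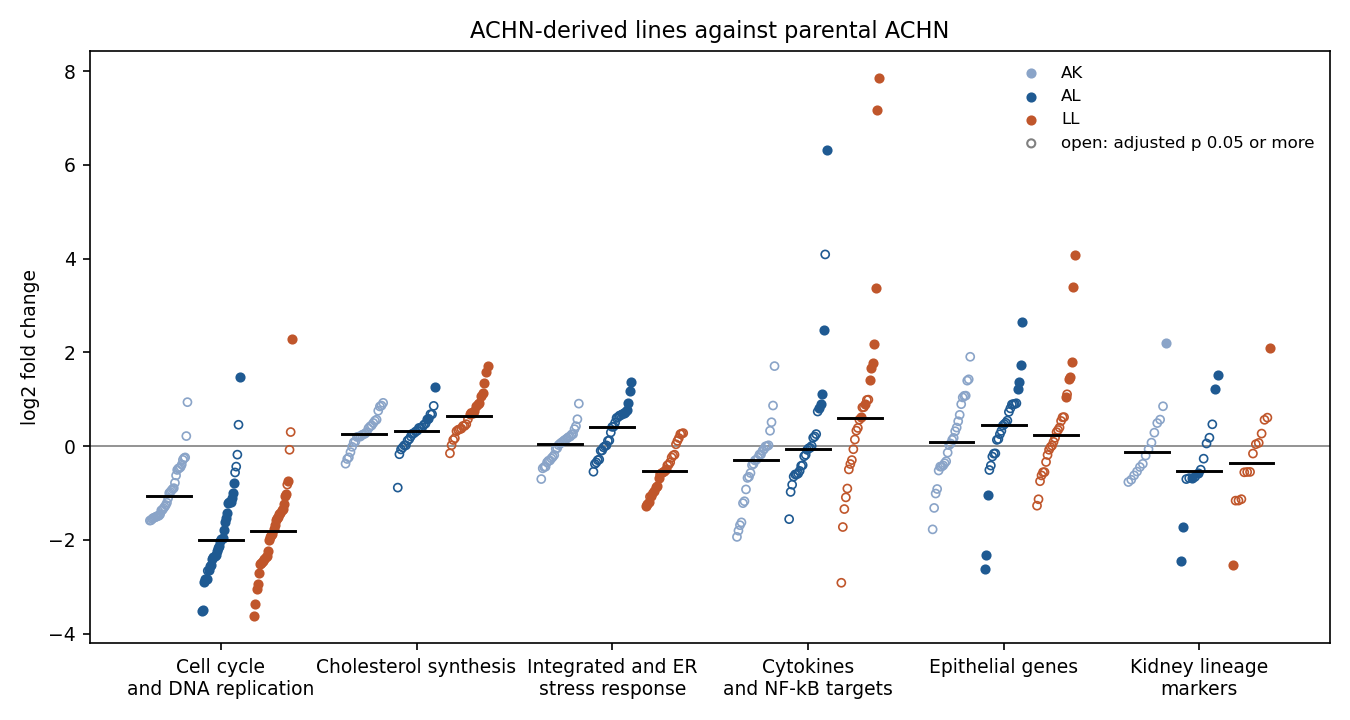
Log2 fold change against parental ACHN of the members of 6 gene lists in AK, AL and LL. Filled points have an edgeR adjusted p under 0.05, open points do not, and the black bar is the list median.

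The CL1 lines were compared with CL1-0 to ask which transcripts separate them. MYADM fell from 192 ± 6.09 CPM in CL1-0 to 104 ± 1.54 in CL1-1, 119.5 ± 2.88 in CL1-3 and 153 ± 10.8 in CL1-5 (n = 2 each), changes of -0.88 ± 0.04, -0.68 ± 0.04 and -0.33 ± 0.04 with edgeR adjusted p of 4.53e-14, 1.06e-12 and 3.24e-07. RHOA changed by 0.29 ± 0.03, -0.45 ± 0.03 and -0.44 ± 0.03, all called. In the order CL1-1, CL1-3 and CL1-5, the protease inhibitor TIMP1 rose by 5.39, 6.69 and 6.53, the receptor kinase AXL by 5.38, 8.51 and 9.79, the cyclin CCND1 by 5.12, 5.46 and 6.16 and the malic enzyme ME1 by 5.32, 7.20 and 7.39. The angiotensin receptor AGTR1 changed by -7.27, -7.53 and -7.66, the guidance gene SLIT2 by -5.09, -7.22 and -6.31 and the ligand WNT5A by -6.49, -7.38 and -4.95. Of 16609 genes tested 4051 were called in the same direction in all 3 lines (1855 higher, 2196 lower) where independent calls would share 1728. The 1728 ignores that CL1-3 and CL1-5 shared 9868 calls in direction, with 1399 opposite. Their fold changes correlated at 0.873 (covariance 4.4), against 0.0884 and 0.0857 (0.245 and 0.238) for each with CL1-1. Simulated sets that share only the CL1-0 libraries, with no changed genes, gave 0.508, 0.512 and 0.501 and lower covariances (0.0731, 0.0733 and 0.073). All lines share the 2 CL1-0 libraries, 1 of which is labelled by treatment as parental CL1-1, and its title (CL1-0) was followed.

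In CL1-1, the steroid reductase AKR1C2 rose from 0.830 ± 0.121 to 263 ± 13.1 CPM (8.31 ± 0.10), the pluripotency gene DPPA2 was at least 1020-fold higher and its partner DPPA4 was higher 222-fold (95% counting interval 75.5 to 1080). CCND1 rose from 5.58 to 194 CPM. The zinc finger gene BNC2 was lower 2390-fold (95% counting interval 429 to 94400), the adaptor SH2D4A 1520-fold (95% counting interval 272 to 60000) and the homeobox gene HOXB5 480-fold (95% counting interval 133 to 3970). The caveolins CAV1 (-4.74 ± 0.06) and CAV2 (-6.35 ± 0.09) fell, with the growth factor TGFB2 (-7.48 ± 0.12) and LOX (-5.73 ± 0.16), while the keratins KRT8 (2.42 ± 0.13) and KRT18 (2.65 ± 0.09) rose. EdgeR called 10853 genes (65.3%), 5352 higher and 5501 lower, with 974 and 1665 at least 2-fold changed. Limma camera called 0 lists (4 at an unadjusted p under 0.05, and 17 by fry), the lowest adjusted p being 0.071 for stress response genes (19 of 27 lower, 4 higher, 21 and 4 adjusted over the list alone, median -0.32), with VLDLR at -3.46 ± 0.23 and the stress factor ATF3 at -1.55 ± 0.10. The mesenchymal median of -0.70 stood at 0.00 with near-zero genes at their bound.

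In CL1-3, the urokinase PLAU rose from 0.378 ± 0.0724 to 911 ± 22.9 CPM (11.21 ± 0.08), the keratin KRT8 from 1.11 to 586 CPM (9.04 ± 0.07) and the ectonucleotidase NT5E by 10.28 ± 0.11. The antiviral GTPase MX1 was higher 368-fold (95% counting interval 126 to 1790) and the synthetase OAS2 at least 125-fold higher. The hypoxia genes EGLN3 (8.57 ± 0.12), ENO2 (7.30 ± 0.09) and NDRG1 (6.93 ± 0.05) rose. The aldehyde dehydrogenase ALDH1A1 fell by 12.81 on the log2 scale, the myosin light chain MYL9 was lower 5490-fold (95% counting interval 1880 to 26600), and the lung lineage factor FOXA2 lower 1160-fold (95% counting interval 320 to 9570). CDKN2A, CDKN2B and MTAP, which lie close together on chromosome 9, were at 0 counts in CL1-3 and at least 772-fold, 112-fold and 790-fold lower. EdgeR called 13547 genes (81.6%), 6952 higher and 6595 lower, with 3493 and 2172 at least 2-fold changed.

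Interferon genes rose in CL1-3 for 24 of 25 and fell for 0 (24 and 0 adjusted over the list alone, median 3.33, or 3.24 with near-zero genes at their bound). Hypoxia genes rose for 26 of 31 and fell for 5 (26 and 5 adjusted over the list alone, median 0.89), protease genes for 20 of 28 and 3 (20 and 3 adjusted over the list alone, median 2.24, or 1.91 at their bound), epithelial genes for 15 of 24 and 6 (15 and 6 adjusted over the list alone, median 2.34) and endothelial genes for 8 of 9 and 1 (8 and 1 adjusted over the list alone, median 3.75, or 3.55 at their bound). Stress response genes fell for 20 of 27 and rose for 6 (20 and 6 adjusted over the list alone, median -0.65). In this order limma camera gave 8.19e-06, 0.00024, 0.00123, 0.0376, 0.042 and 0.00933, or adjusted p = 0.101, 0.223, 0.223, 0.223, 0.223 and 0.281 with an estimated correlation. The other lists stood at 0.0781 to 0.907 by camera.

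In CL1-5, the chemokine CXCL8 was at 0 counts in CL1-0 and at least 2750-fold higher, IL6 at least 310-fold and CXCL1 at least 182-fold. The hyaluronan receptor CD44 rose by 11.94 ± 0.10, PLAU by 11.43 ± 0.08 and the GTPase RAC2 by 10.05 ± 0.17. The antitrypsin gene SERPINA1 was at least 3190-fold higher and the GTPase regulator ARHGDIB at least 150-fold. SLC2A3 fell from 1435 ± 16.2 to 32.2 ± 0.0723 CPM (-5.48 ± 0.04), MYL9 was lower 5170-fold (95% counting interval 1770 to 25100) and CDKN2A 2180-fold (95% counting interval 391 to 86100), and MTAP was at least 744-fold lower. EdgeR called 12974 genes (78.1%), 6613 higher and 6361 lower, with 2795 and 2273 at least 2-fold changed.

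Hypoxia genes rose in CL1-5 for 27 of 31 and fell for 2 (27 and 2 adjusted over the list alone, median 0.76), protease genes for 20 of 28 and 4 (20 and 4 adjusted over the list alone, median 1.84, or 1.52 with near-zero genes at their bound), interferon genes for 19 of 25 and 3 (19 and 3 adjusted over the list alone, median 2.51) and cytokine genes for 17 of 22 and 4 (17 and 4 adjusted over the list alone, median 3.72, or 2.98 at their bound). In this order limma camera gave 4.08e-05, 0.000371, 0.00168 and 0.0144, or adjusted p = 0.238, 0.211, 0.211 and 0.211 with an estimated correlation. The other lists stood at 0.0668 to 0.976 by camera.

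**Figure D5:**
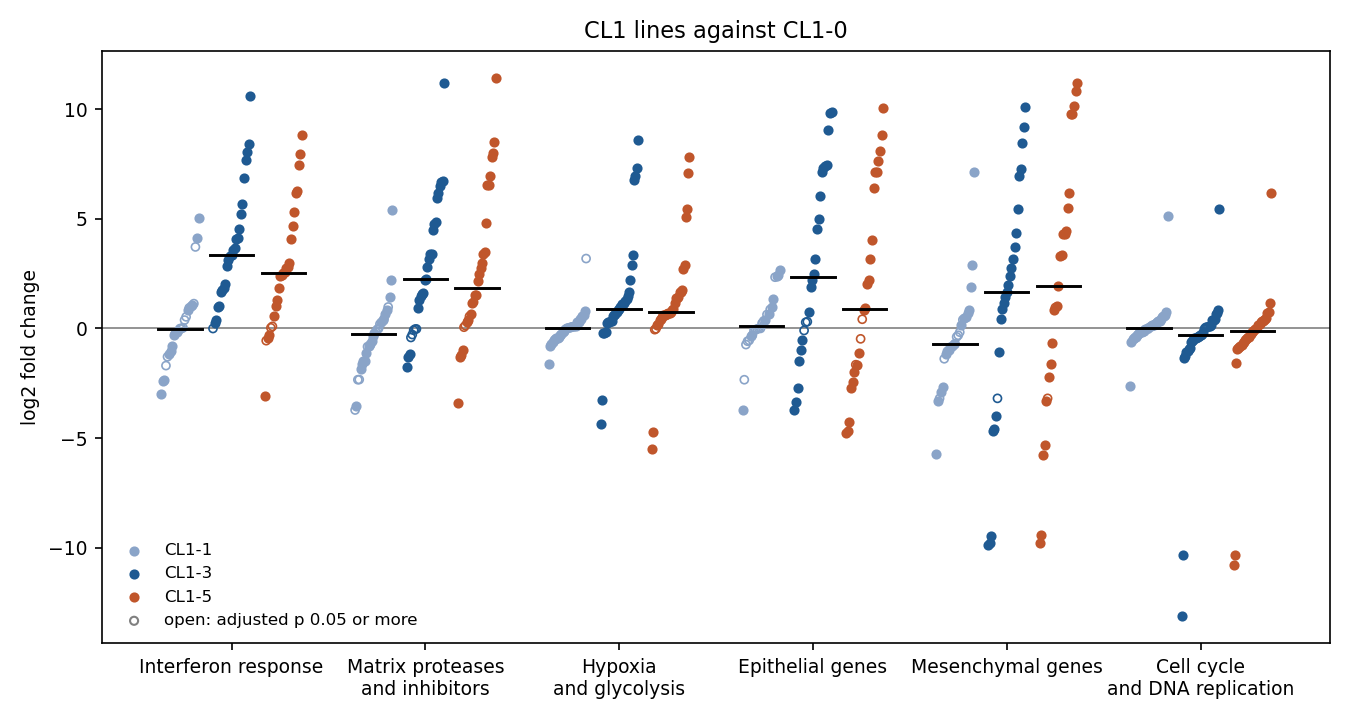
Log2 fold change against CL1-0 of the members of selected gene lists in CL1-1, CL1-3 and CL1-5. Filled points have an edgeR adjusted p under 0.05, open points do not, and the black bar is the list median.

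ATAC-seq asks where chromatin opens or closes, and all values come from the authors' deposited tables, which give 1 pooled value per group. In the authors' deposited table for shMYADM#1 a promoter region of Myadm (chromosome 7, mm10, from 3290187 to 3290738) had a signal of 48.3 against 38.9 in control (log2 ratio 0.31, p = 0.027), a second 43.9 against 38.0 (0.21, p = 0.21), and the promoter region of Rhoa a log2 ratio of 0.02 (p = 0.59). Regions near Mir7j (3.75), Apcs (3.59) and Tmtc2 (3.21) gained most and regions near Mir12198 (-3.95), Crispld2 (-3.35) and Elfn1 (-3.30) lost most in that authors' deposited table. The authors' deposited table holds 107583 regions, of which 13621 had p under 0.05 (6083 higher, 7538 lower, at 2-fold 1269 and 3636, at promoters 823 and 418), where chance alone gives 5379 and Benjamini-Hochberg adjustment leaves 1517, and the table does not name its test. Promoters of genes with higher RNA had a median log2 ratio of 0.0513 in the authors' deposited table and those of genes with lower RNA 0.0297 (0.0543 for genes not called), a difference of 0.0215 (permutation of 7148 genes, p = 0.0234), or 0.0165 with all regions assigned to a gene (p = 0.114).

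For shRhoA, the authors' deposited table gives the first Myadm promoter region a signal of 37.5 against 38.9 in its own control group (titled Vector) (-0.05, p = 0.943), the second 41.3 against 36.2 (0.19, p = 0.045) and the Rhoa promoter region 45.5 against 49.4 (-0.12, p = 0.246). The promoter region of Dapk1 fell to 0.554 against 7.07 (-3.67) and that of Htatip2 to 11.9 against 41.1 (-1.79) in the authors' deposited table. Regions near Sh3kbp1 (5.12), Tmtc2 (4.96) and Bnc2 (4.93) gained most and those near Pantr1 (-4.71), Cadps2 (-4.67) and Caln1 (-4.59) lost most in the authors' deposited table. The authors' deposited table holds 106433 regions, of which 51195 had p under 0.05 (25459 higher, 25736 lower, at 2-fold 9498 and 12671, at promoters 2594 and 1969), where chance alone gives 5322 and Benjamini-Hochberg adjustment leaves 43313. Promoters of genes with higher RNA stood at a median of 0.0585 and those with lower RNA at -0.0815 (-0.0192 for genes not called) in the authors' deposited table, a difference of 0.14 (permutation p = 1e-05, the smallest the permutations can give).

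For BMM, the authors' deposited table does not say which group is the numerator, so its signs are given as deposited and the group that a positive value favours stays open. The Myadm promoter regions stood at 0.155 and -0.0253 in the authors' deposited table (adjusted p = 0.626 and 0.966 as the table gives them) and that of Rhoa at 0.29 (adjusted p = 0.0612). Regions near Gm35612 (7.57), Firre (7.34) and Xist (7.19) had the highest values in the authors' deposited table and regions near Eif2s3y (-9.09), Uty (-7.99) and Ddx3y (-7.97) on chromosome Y the lowest. The authors' deposited table holds 83952 regions, of which 1371 were called, and 1326 of these lie on autosomes (668 positive and 658 negative). At 2-fold 96 regions were positive and 474 negative, and at promoters 330 and 22. Promoters of genes with higher RNA in the knockout stood at a median of 0.261 and those with lower RNA at 0.172 (0.222 for genes not called) in the authors' deposited table, a difference of 0.0891 (permutation p = 1e-05, the smallest the permutations can give). With the knockout as numerator the promoters go with the RNA, and with wild type as numerator all these signs turn and they go against it.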

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

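Of the tests in this part, those on the shared 4T1 changes, on the BMM cell types, on MCF10A libraries made apart and on other splits of the samples were chosen after the result was seen. Differences between the 4T1 groups stand out because a direct test called them. Myadm was higher by 0.86 and Rhoa by 0.20 in shMYADM#2 than in shMYADM#1, which carry the same named target, and 3833 genes were called between these groups. The cell cycle list differed by a median of 1.22 and the cholesterol list by 1.41. Against the mean of both shMYADM groups, shRhoA was higher for Myadm by 1.28 and lower for Rhoa (-0.27), with 7137 genes called. Each is a tested difference between groups. No group holds 4 samples, so no single sample was tested as an outlier.

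Other splits were counted for each 4T1 result, 10 for 3 against 3 samples, too few for a share under 0.05. The real split alone reached its gene count: 4395, 6567, 6707 and 3833 for shMYADM#1, shMYADM#2, shRhoA and the direct shRNA contrast (highest other 0). Called lists were 9, 7 and 8 against control (highest other 8, 6 and 7). In the direct contrast 2 splits reached the real 4 (highest other 5). Some splits with 0 genes called gave nearly as many lists, so camera counts do not mark the real groups. Of 100 drawn splits, the real one led for the 3528 genes called with both MYADM shRNAs (highest other 2841). So it did for the 2067 shared with shRhoA and the 7137 of shRhoA against the mean of both (highest other 0 and 5390). The 7 lists of that contrast were reached by 17 splits (highest other 7). Splits mix unlike groups and replicates may not be separate cultures, so chance stays open.

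The first pattern weighed is that 3 knockdown-labelled 4T1 groups share changes against the same 3 control libraries. Control libraries that differ alike from all other groups cannot be told apart from a shared change, since 1 control group serves all 3 comparisons, and 24.8% of the shared genes were called in neither direct contrast between the groups. Changes that follow the Myadm transcript would be smaller with shMYADM#2, yet the median ratio of its change to that of shMYADM#1 was 1.31 (72.8% of genes changed more with shMYADM#2). A scaling factor moves all genes of a library alike, yet the cell cycle and interferon medians lie 2.03, 3.74 and 3.56 apart (permutation p = 1e-05 each). Both lists were picked after these medians were seen, so the p-values overstate the evidence. That factor leaves gaps between lists unchanged, so it is not the whole cause. Protein loss without transcript loss, other shRNA targets and growth state stay open as untested.

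In the BMM knockout, mast cell, endothelial and erythroid transcripts are higher and macrophage transcripts lower. A lower share of macrophages with all other cell types in proportion would raise every other list alike, but the mast cell median exceeds the stromal median by 3.23 (exact permutation p = 0.00583 over genes). Sex of the animals behind the RNA libraries leaves Y-linked counts in males, and the largest count of 4 Y-linked genes in any library was 2. Scaling by a few abundant genes moves all lists alike, while the macrophage median lies -3.96 from the mast cell median (exact permutation p = 0.000242 over genes). A changed mixture of particular cell types and a change within cells may both contribute, and these 2 against 2 bulk libraries do not separate them.

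In MCF10A, the libraries part by replicate number more than by group. Deviations of same-numbered libraries from their group means correlate at 0.825, which goes with numbers made or sequenced apart, a candidate explanation that the labels do not record. Erythroid markers not yet looked at had 139 counts in replicate 1 against 191 in replicate 2, which argues against trace erythroid reads in replicate 1, although the embryonic globin HBE1 stood at 38.2 and 38.5 CPM there. Neuronal markers not yet looked at had 646 counts in replicate 2 and 45 in replicate 1, with most in few genes, so reads of sympathetic neurons cannot be told apart from a difference within the cells. Trace reads of other cells as the whole split are argued against by 1038 of 8899 well-expressed genes that differ at least 2-fold between the numbers, against 23 between the groups.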

How the results depend on the processing

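Of the tests in this part, those with the longest transcript, crossed pairing, neither control replicate 2 nor shRhoA replicate 1, alternatives of the direct contrasts, adjusted ATAC p, unadjusted p in the second comparison and 2 derived lines were chosen after the data were seen. Where 1 library was left out of a group of 2, the lone sample is assumed to vary like the other groups. The cause of a shift was not tested unless the setting itself names it.

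Genes the text may name kept direction and side of the threshold in 11249 of the settings tried, lost their call in 430, gained 1 in 9 and reversed in 0. All alternatives left 71 of 72 named genes unchanged for shMYADM#1, 90 of 91 for shMYADM#2, 66 of 67 for shRhoA, 70 of 102 for BMM, 18 of 20 for MCF10A, 12 of 32 for AK, 26 of 73 for AL, 44 of 74 for LL, 101 of 102 for CL1-1, 109 of 109 for CL1-3 and 113 of 113 for CL1-5. Myadm with shMYADM#2 passed the threshold with the longest transcript (-0.18, edgeR adjusted p = 0.0405) and with neither control replicate 2 nor shRhoA replicate 1 (-0.14, edgeR adjusted p = 0.0324). MYADM in MCF10A passed with a replicate block (4.05, edgeR adjusted p = 0.022) and with the DESeq2 Wald test (4.23, DESeq2 adjusted p = 4.64e-06), and ranged from 3.14 to 4.85 with 1 library left out, called at 4.85 without MYADM replicate 2.

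Counts of called genes stayed within 1.5 times in most settings. With 1 library left out at a time, in BMM they ran from 908 without knockout replicate 2 to 6739 without wild-type replicate 2, in MCF10A from 0 to 16, in AK from 2 to 849, in AL from 142 to 7104 and in LL from 602 to 876. In MCF10A the replicate block called 432 genes and the Wald test 16. In AK, no filter called 1139, the Wald test 890, limma on FPKM 49 with a pseudocount of 1 and 51 with 0.1, and the 2 groups alone 158. In AL, no filter called 3702 and the 2 groups alone 875, and in LL the 2 groups alone called 8522. With neither control replicate 2 nor shRhoA replicate 1, shMYADM#2 against shMYADM#1 called 7073.

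Replicate numbers come from the titles, and nothing says that they pair libraries. Same-numbered libraries deviated together in MCF10A (correlation 0.825) and oppositely in BMM (-0.486), where the crossed pairing called 5707 genes. In 4T1, 7 of 18 pairs of same-numbered libraries exceeded 0.1 (-0.723 to 0.474), and correlations ran from -0.125 to 0.117 in ACHN and -0.142 to 0.0642 in CL1.

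Shared calls with both MYADM shRNAs numbered 2048 at 1.5-fold and 1111 with shRhoA. All 3 ACHN lines shared 587 genes by the Wald test, and AL with LL alone 1524, while the CL1 lines shared 1292 at 1.5-fold, and CL1-3 with CL1-5 alone 9868. Genes opposite in MCF10A to the MYADM shRNAs were 35 with the replicate block (36 in the same direction) and 12 at unadjusted p (10), and genes shared with BMM were 422 at 1.5-fold, 402 with the replicate block and 1061 at unadjusted p.

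Lists called with an estimated correlation fell to 4 for shMYADM#1, 2 for shMYADM#2, 3 for shRhoA and 0 for BMM, MCF10A, AK, AL, LL, CL1-3 and CL1-5. With fry in limma they were 15, 14, 17, 19 and 0 for shMYADM#1, shMYADM#2, shRhoA, BMM and MCF10A, 0 for AK and LL, and 17, 21 and 18 for CL1-1, CL1-3 and CL1-5. The replicate block gave 1 for AK. With 1 library left out, BMM gave 10 to 15 lists, MCF10A 1 to 8, AK 1 to 3, AL 3 to 7 and LL 5 to 7. By fry these lists turned direction: MARVEL genes with shMYADM#1 (adjusted p = 4.32e-05) and in CL1-3 (2.46e-05), Wnt genes with shMYADM#1 (0.0293) and in CL1-1 (0.00502), and cholesterol and lung lineage genes in CL1-3 (0.00111 and 0.0109). In MCF10A by limma camera, cell cycle genes turned without vector replicate 2 (adjusted p = 0.0484, range 1.02e-05 to 0.645 with 1 library left out) and Wnt genes without vector replicate 1 (0.927) and without MYADM replicate 2 (0.877, range 0.00122 to 0.927). Other single lists were the same in 1516 settings, gained a call in 124 and lost 1 in 96.

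In the authors' deposited ATAC tables, Benjamini-Hochberg adjustment left 1517 regions for shMYADM#1 at 0.05 and 548 at 0.01, with 4905 at 2-fold. For shRhoA the authors' deposited table held 31654 at an adjusted p of 0.01 and 22169 at 2-fold, and for BMM 303 at 0.01 and 570 at 2-fold. The promoter difference for shMYADM#1 was 0.0165 (permutation p = 0.114) with all regions in the authors' deposited table. Alternatives by library were not run for ATAC, which has 1 value per group here.

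Depth limits genes near the floor of 3 counts over a group, and the spread between libraries limits the MCF10A count.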

Other observations

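Of the tests in this part, those on ATAC sex chromosomes were chosen after the result was seen. Genes named by the rule that fit no list above include RIN2, an endocytic regulator, which was at 0 counts in CL1-0 and at least 1690-fold higher in CL1-3 and 1640-fold in CL1-5. In CL1-3 the granzyme inhibitor SERPINB9 was at least 1450-fold and the raft gene MALL, of the same family as MYADM, at least 935-fold higher. In BMM without MYADM the progenitor receptor Flt3 (2.92 ± 0.35) and the dendritic cell genes Zbtb46 (2.90 ± 0.48) and Siglech (2.34 ± 0.29) were higher, as were the monocyte genes Plac8 (2.65 ± 0.25) and Ly6c2 (2.09 ± 0.34).

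Haemoglobin genes held at most 6.3e-05% of counts in ACHN libraries other than parental replicate 2 and AK replicate 1. Ribosomal protein genes held 6.95 and 6.66% in parental ACHN, 9.25 and 7.77% in AK, 14.7 and 9.16% in AL and 13.2 and 13.0% in LL.

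CDKN2A and MTAP had no or almost no reads in CL1-3 and CL1-5, and loss of a stretch of the genome may be the reason. A run of at least 3 neighbouring genes silent in both lines was found 1 time, with KLHL9, MTAP and CDKN2A on chromosome 9 (hg19, from 21329664 to 21994490) at 21.0, 34.3 and 33.5 CPM in CL1-0. The genes on either side, FOCAD and TUSC1, were expressed. Among 1000 shuffled orders of genes 2 held such a run, and none more than 1, so 1 run equals the highest that chance gave. Only genes at 5 CPM or more in CL1-0 entered the order, so genes below that are skipped, which leaves the length of a loss open.

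In the authors' deposited BMM ATAC table, 10 of 12 regions on chromosome Y were called with a negative value and 3 of 3 regions at Xist with a positive one, which is consistent with animals of different sex behind the ATAC groups. The deposited table gives no value per library, so this rests on 1 comparison. In the BMM RNA libraries, Y-linked counts were 0, 0, 2 and 1 and Xist stood at 21.4 and 34.3 CPM in wild type against 93.4 and 106 CPM in the knockout.

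Dapk1, a death-associated kinase, stood at 14.8 CPM in 4T1 controls and at 0.0549, 0.134 and 0.119 CPM in the shMYADM#1, shMYADM#2 and shRhoA groups, and a closed promoter or silencing of each group by itself may underlie this. For closed promoters, the log2 promoter ratio in the authors' deposited table for shMYADM#1 was 0.718, towards opening, and in that for shRhoA -3.67, towards closing, but 1 gene gives no spread. For silencing of each group by itself, 1 gene met the bounds where the product of the shares of silent genes gives 9.5e-08, a product that takes all genes as equally prone to silence and ignores the shared controls. These tests leave both open.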
